A study of Arabidopsis thaliana with 2 samples.

How the data were processed

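The data were SPARE libraries of Arabidopsis thaliana, 1 of the fiery mutant and 1 of wild type Col-0. Per the labels' protocols, total RNA was depleted of ribosomal RNA, an RNA adaptor was ligated to free 5′ ends, the RNA was reverse transcribed in multiplex with precursor-specific primers, and the products were amplified in 18 PCR cycles, gel purified and sequenced. Per the submitters' processing notes, Bowtie and TAIR10 were used. The version and settings of the aligner are not given in the sources used here. The deposited files list, for each precursor name, sequence tags and their abundance, which are whole-number read counts that the authors did not normalise as far as the values show. The precursor name of each tag is the authors' own.

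Tags were matched again to the TAIR10.1 reference (RefSeq annotation, 1-based coordinates) by exact search on both strands with a 26 nt seed. All 1755 fiery and 677 wild-type tags matched. Tags with more than 1 match held 8.07% of the fiery and 19.4% of the wild-type reads, of which 75 and 31 reads lay outside mir405. The match nearest the annotated precursor of the given name was used. All 153 names were found in the annotation, 8 of them after a change of the suffix letter. The names mir405a, mir405b and mir405d were counted together, since the 2 files list the same tags under different copies, which left 151 precursors. Of these, 112 had 1 annotated mature RNA on the 3′ arm, 3 had 2 and 36 had none. The arm came from the product name or, where it gives none, from RNAfold. Loop-side and base-side ends were counted within 1 nt of the annotated mature RNA, only in precursors with 1 mature RNA on that arm. Antisense tags (152 fiery and 32 wild-type reads) were left out of end positions, so that mir835 and mir844 had none.

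Shares of library reads carry exact Clopper-Pearson 95% intervals. Ratios of shares (fiery over wild type) carry exact conditional binomial intervals for precursors with at least 100 reads in both libraries together. End positions needed at least 30 reads in the library. With 1 library per group there was no test between groups and no p-value. Lists were set against 10000 random lists of the same size, matched on mean reads in 5 bins. The lists of families were fixed before the data were examined, as were the minimum counts and the rule for named precursors. That rule took the 10 with the most reads in each library, the 12 highest and 12 lowest ratios, up to 10 with at least 30 reads in both libraries whose main end differed by more than 1 nt, and 2 to 4 examples per list. Other precursors named (mir163, mir394b, mir841, mir862, mir870, mir835, mir844, and those named as sharing the main end) were chosen after their values were seen. Chosen after the data were seen were the window of 20 to 23 nt, the counting of the mir405 copies together, and 4 alternatives: only tags longer than 35 nt, at least 10 reads at the 2 cuts, a 3′ arm taken from the fold where none is annotated, and leaving out precursors whose base-side cut would give a tag length absent from a library. mir157 counted among the other families because its number was not on the conserved list.

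The methods were tested on simulated data. With counts drawn for 48 precursor names at the real depths, the interval of the ratio held the true value in 95.6% of draws with no difference, in 95.3% at 2-fold and in 95.8% at 10-fold. It excluded 1 in 4.43%, 97.2% and 100% of them. These counts were independent Poisson draws, close to what the interval assumes, so the check does not cover duplication by PCR. Tags taken from the genome at the cuts of 114 precursors were placed correctly in 100% of cases. They came from the named precursors, which the nearest-match rule favours, so this check could hardly fail. Of 200 lists drawn at random, 3.5% lay outside percentiles 2.5 to 97.5. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and RNAfold 2.7.2.

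Read counts depend on the primers and on PCR, so that shares compare the same precursor between libraries and not different precursors with each other. Tags end at 40 nt in fiery and 50 nt in wild type. No tag had 36 to 39 nt in fiery or 46 to 49 nt in wild type, so that ends giving fragments of those lengths could not be seen. The tag length that a cut would give was inferred from the most frequent 3′ end of the short tags, which can be wrong. For mir841 it gave 49 nt at the base-side cut, yet its wild-type main end lay at that cut (7 of 32 reads). The alternatives tried were other minimum counts, windows, tags with a single match, pooled reads, scaling by the median ratio, leaving out the most abundant precursor of each library, thinning of the fiery library to the wild-type depth, distinct tags counted once, and each family counted once.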

Results

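The sites at which microRNA precursors of Arabidopsis thaliana were cut were read by SPARE, an assay that ligates an adaptor to the 5′ ends of RNA fragments and copies them with primers placed downstream in each precursor. There was 1 library of a mutant named in the labels only as fiery and 1 library of wild-type Col-0. Each came from a mixture of seedlings of 2 weeks and of leaves and inflorescences of plants of 5 weeks. The fiery library held 33192 reads in 1755 distinct tags, and the wild-type library held 12129 reads in 677 distinct tags. The mutated gene itself was not measured by this assay, so the genotype labels had no check in these data. The differences between the libraries have no replicate check. Intervals are exact 95% intervals (Clopper-Pearson for shares, conditional binomial for ratios) and cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

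The first question was which precursors gave fragments. In the fiery library, mir398c and mir398b, precursors of the RNA that targets copper and zinc superoxide dismutases, held 18.3% and 14.3% of the reads. They were followed by mir168a, whose product targets ARGONAUTE1, with 8.87%, by mir405 (copies a, b and d counted together) with 7.85%, and by mir164b, whose product targets NAC transcription factors, with 5.95%. In wild type, mir172a, whose product targets AP2-like factors of flowering, held 28.2%. It was followed by mir405 with 19.2%, mir168a with 7.97%, mir166b with 3.31% and mir447a with 3.10%. The next precursors by reads were mir779, mir822, mir472a, mir863 and mir161 in fiery, and mir171b, mir447b, mir779, mir822 and mir416 in wild type. The 10 precursors with the most reads held 73.3% of the fiery reads and 72.1% of the wild-type reads. At least 10 reads were found for 93 of the 137 precursors listed in fiery and for 76 of the 122 listed in wild type. A precursor with no read could hold up to 0.00904% of the fiery library and up to 0.0247% of the wild-type library (3 counts). The tags differed in length between the libraries. They reached 40 nt in fiery and 50 nt in wild type, and tags of 35 nt or less held 22.4% (21.9 to 22.8) of the fiery reads and 65.6% (64.7 to 66.4) of the wild-type reads.

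**Figure D1:**
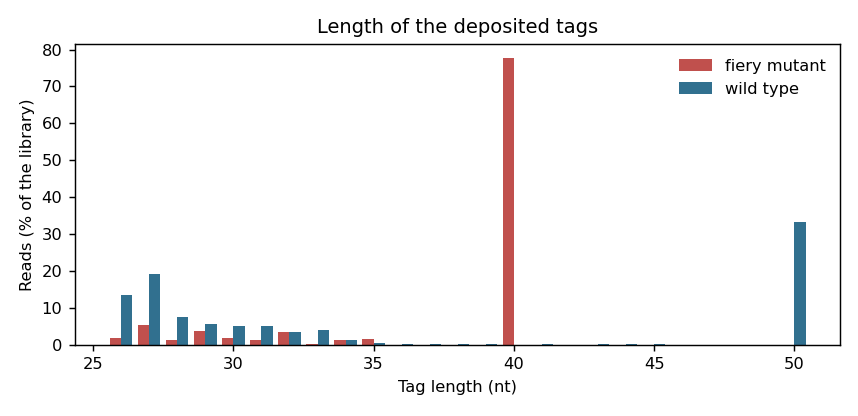
Reads by tag length in nt, as percent of each library, for the fiery library (red) and the wild-type library (blue). Tags at the longest length held 77.6% of the fiery reads (40 nt) and 33.2% of the wild-type reads (50 nt).

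The second question was where the main 5′ end of each precursor lay. On the 3′ arm, an end at the first nucleotide of the mature RNA is left by a cut on the side of the loop, and an end at the first nucleotide after it is left by a cut on the side of the base. In fiery, most precursors with enough reads had their main end at the base-side cut. In wild type this majority was small and was lost with a lower minimum of reads. mir168a had 94.8% of its fiery reads and 89.2% of its wild-type reads at chromosome 4, position 10578758, directly after its mature RNA (annotated precursor on the plus strand, 10578635 to 10578772, outside protein-coding genes). mir398b had 78.7% (fiery) and 87.2% (wild type) of its reads at chromosome 5, position 4691128. Its main fiery tag was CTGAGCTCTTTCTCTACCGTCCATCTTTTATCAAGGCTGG, with 3726 reads, and its precursor (4691022 to 4691137, plus strand) lies opposite AT5G14550. mir398c had 58.4% of its fiery reads at chromosome 5, position 4694799, with the tag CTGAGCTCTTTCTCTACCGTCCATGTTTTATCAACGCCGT, and 21.1% at the next nucleotide. mir164b had 74.0% of its fiery reads at the base-side cut, at chromosome 5, position 287737. Over precursors with at least 30 reads, the main end held a median of 66.0% of the reads in fiery (57 precursors) and 57.1% in wild type (45 precursors). Among those with 1 annotated mature RNA on the 3′ arm, it lay within 1 nt of the base-side cut in 34 of 50 in fiery and 19 of 35 in wild type. With at least 10 reads per precursor these were 44 of 72 and 26 of 58.

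A smaller group of precursors had its main end 20 to 23 nt beyond the base-side cut, about the length of a microRNA duplex further down the stem. mir822 had its main end 22 nt beyond the cut in both libraries, with 71.6% of the fiery and 87.6% of the wild-type reads (chromosome 5, position 897044). mir163 had it 21 nt beyond the cut in both libraries, with 81.0% and 30.8%. mir472a, whose product targets disease resistance genes, had 72.1% of its fiery reads 21 nt beyond the cut, at chromosome 1, position 4182121, inside the protein-coding gene AT1G12290. mir447b (60.1%) and mir394b (53.2%) had theirs 21 nt beyond the cut in wild type, and mir862 (43.2%) in fiery. Among precursors with 1 annotated mature RNA on the 3′ arm, these 6 were the only ones with a main end in that window. The window was set after the data were seen. For mir394b the base-side cut would give a tag of 48 nt, a length absent from wild type, so that its main end there could not be compared with that cut. Over all reads of precursors with 1 annotated mature RNA on the 3′ arm, 63.1% (62.6 to 63.7) were at the base-side cut in fiery and 26.2% (25.3 to 27.0) in wild type. Ends over 23 nt beyond it held 9.29% (8.97 to 9.63) in fiery and 52.0% (51.1 to 53.0) in wild type, where mir172a had most of its reads. mir405 also had its main end there, 25 nt beyond the cut, mostly in a tag of 27 nt (58.5% of its fiery and 57.1% of its wild-type reads). It had no read at either annotated cut, so its large share of both libraries does not show cutting at those sites. As means over precursors with at least 30 reads (52 in fiery, 35 in wild type), the base-side cut held 52.8% and 41.9%. Ends over 23 nt beyond it held 6.74% and 18.2%. The medians were 69.7% and 22.2% at the cut, and 0.136% and 2.86% over 23 nt beyond it. The pooled difference in ends over 23 nt beyond the cut thus came largely from a few precursors. At the base-side cut the median precursor differed as well.

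**Figure D2:**
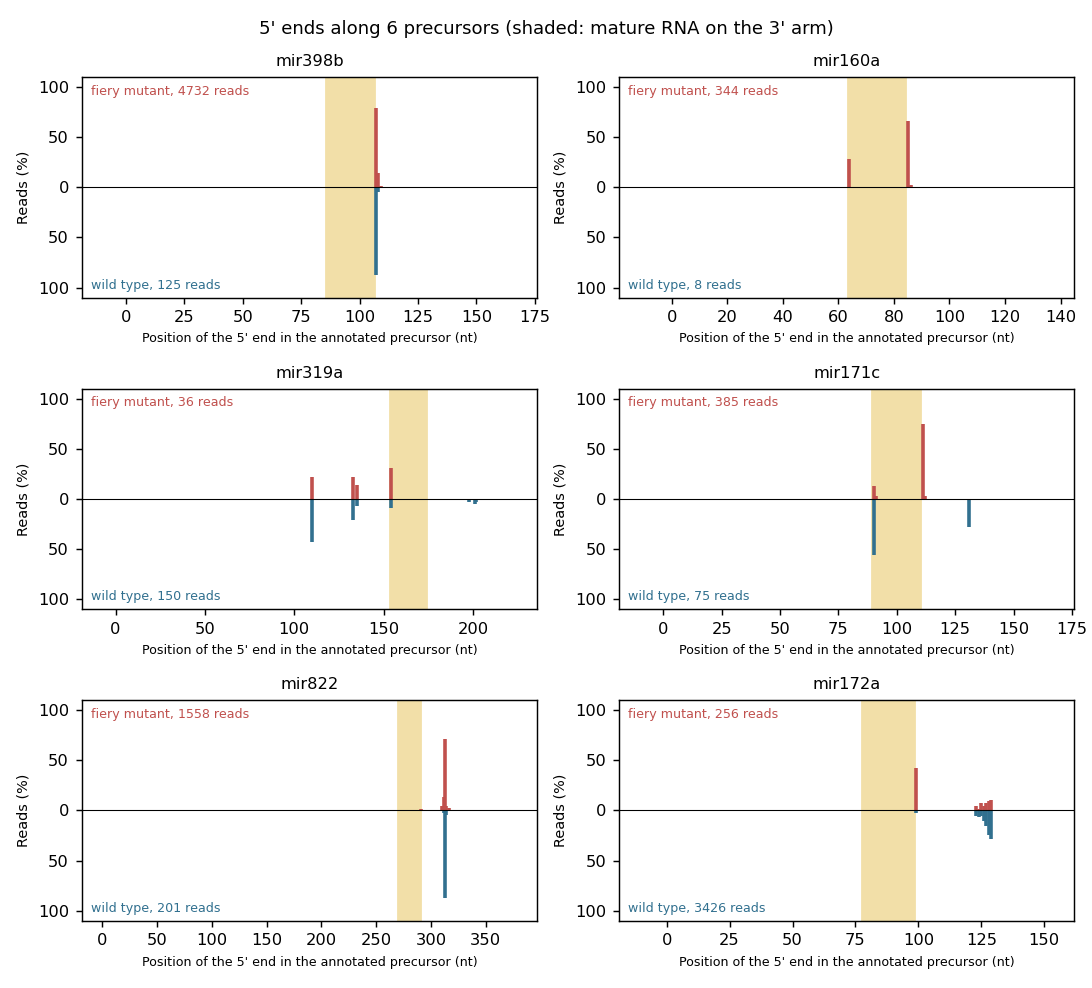
Positions of 5′ ends with at least 5 reads along 6 precursors, in nt from the start of the annotated precursor, as percent of the precursor's reads (fiery upward in red, wild type downward in blue; the mature RNA on the 3′ arm is shaded). mir398b ended at the base-side cut, mir160a at both cuts, mir319a at several upstream positions, and mir822 at 22 nt beyond the base-side cut; mir160a had 8 wild-type reads, which are not drawn.

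The third question was the order of the cuts, described by the loop-side share, the loop-side reads among those at either cut. A loop-side end shows a cut near the loop made before the cut near the base. A base-side end is left whichever cut came first, so a low share does not show that the base was cut first. Loop-side ends made up a large share in some precursors, such as mir156d and mir160a, with wide differences within families, and were rare in most precursors of the families reported to be cut from the base. The families reported by earlier work as cut from the loop in short hairpins had a median loop-side share of 19.4% over 8 precursors in fiery and 20.1% over 5 in wild type. These medians were at percentile 95.7 and 90.6 of 10000 random lists of precursors matched on reads, as a description of these libraries. The wild-type median was not stable: it was 10.1% at the exact position or with at least 100 reads, 41.9% with only tags longer than 35 nt and 60% with at least 10 reads per precursor. In fiery, mir156c, with the most reads of this list, had a loop-side share of 5.54% (3.82 to 7.73), mir171c of 16.9% (13.2 to 21.2), mir160a of 29.6% (24.8 to 34.9) and mir156d of 49.3% (42.3 to 56.3). In wild type, mir171b had 20.1% (14.4 to 27.0), mir171c 97.7% (88.0 to 99.9) and mir160c 63.6% (40.7 to 82.8). In both libraries, mir171a of the same list had no loop-side read, among 90 base-side reads in fiery and 127 in wild type. miR156 targets SPL factors, miR160 targets auxin response factors and miR171 targets GRAS-domain factors.

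The families reported as cut in several steps from the loop, miR159 and miR319, had a median loop-side share of 23.5% over 3 precursors in fiery and 70.8% over 4 in wild type, at percentiles 81.2 and 98.9. The wild-type median lay between mir159b (2 of 3 reads at the cuts) and mir319b (6 of 8), while mir319c had 0 of 82. It was 22.0% with reads pooled, 50% with at least 10 reads at the 2 cuts and 0% with only tags longer than 35 nt, so it is not a stable value. The share of mir319a in these medians (91.7% and 100%) is no measure of the order of cuts. Its loop-side tags, 27 to 29 nt long, all ended 7 nt past the base-side cut, and from that 3′ end a base-side tag would be too short to be read. Without precursors of this kind the medians were 16.3% and 66.7%, the latter from 3 precursors. miR319 targets TCP factors of leaf growth. mir319a had its ends in wild type at nt 110, 133 and 154 of the precursor (64, 31 and 13 reads), and the same 3 positions held 8, 8 and 11 reads in fiery. Position 154 is the loop-side cut, and the others lie 21 and 44 nt upstream of it. mir319b had 35 of its 55 wild-type reads 44 nt upstream of the loop-side cut. mir319c had 38 and 32 wild-type reads 24 and 23 nt upstream of the loop-side cut, and 36 and 39 within 1 nt of the base-side cut. The families reported as cut from the base had a median of 0.0113% over 12 precursors in fiery and 0% over 10 in wild type. Their main end was at the base-side cut in 12 of 12 precursors in fiery and 8 of 10 in wild type. Among these, mir398b had 1 loop-side and 4405 base-side reads in fiery, and mir168a had 0 and 2887, while mir390b had a loop-side share of 15.2% (5.11 to 31.9). The 3 lists come from earlier reports on Arabidopsis precursors, which may include work on these samples, so they are not independent evidence of direction. Over all precursors the median loop-side share was 1.51% over 46 in fiery and 0% over 30 in wild type. The fiery median was 0% with at least 10 reads per precursor or at the exact position, 0.190% with at least 100 reads and 0.366% with at least 10 reads at the 2 cuts, so it did not set the libraries apart.

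**Figure D3:**
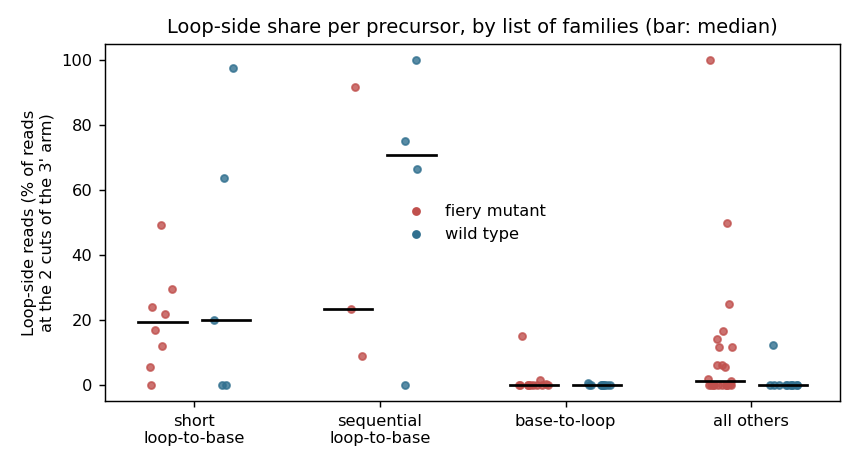
Loop-side reads as percent of the reads at the 2 cuts of the 3′ arm, 1 point per precursor with at least 30 reads, in fiery (red) and wild type (blue), by list of families, with the median as a bar. Medians were 19.4% and 20.1% in the short loop-to-base list and 0.0113% and 0% in the base-to-loop list; a few points rest on a single read at the cuts, as mir870 at 100%.

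The fourth question was which precursors differed in share between fiery and wild type. The miR398 precursors, with the most fiery reads, had higher shares in fiery: mir398c was 49.4-fold higher in fiery (36.9 to 67.9) and mir398b 13.8-fold higher (11.6 to 16.7). Of the 45 wild-type reads of mir398c, 37 lay over 200 nt from the precursor, and the reads within 200 nt (5681 in fiery and 8 in wild type) gave a ratio of 259 (132 to 601). mir472a was 91.1-fold higher (35.5 to 335, 997 against 4 reads), mir164b 42.4-fold (26.4 to 73.0) and mir158a 37.9-fold (14.7 to 140). mir395b, whose product targets sulfate assimilation genes, gave a ratio of 51.9 (9.16 to 2064) from 142 reads against 1. The other precursors with the highest ratios were mir156c (24.0), mir863 (19.3), mir160a (15.7), mir824 (8.70), mir156d (8.62) and mir169a (8.38). All 17 wild-type reads of mir863 lay over 200 nt from the precursor, and its 742 nearer fiery reads made it at least 90.4-fold higher there by the floor of 3 counts, with an exact lower limit of 73.3.

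The fiery share was lowest against wild type for mir447b, which was 194-fold higher in wild type (74.8 to 715, 4 against 283 reads). mir393a, whose product targets auxin receptors, was 95.8-fold higher in wild type (36.6 to 356), mir447a 39.6-fold (26.6 to 61.4) and mir172a 36.6-fold (32.2 to 41.7). They were followed by mir414 (25.1), mir171b (17.4), mir845b (14.7), mir319c (12.5), mir319a (11.4), mir166b (6.06), mir390a (5.04) and mir172d (4.83). Of 47 precursors with at least 100 reads in both libraries together, the interval of the ratio lay above 1 for 23 and below 1 for 18, and held 1 for 6. The median ratio of the 31 precursors with at least 30 reads in each library was 0.520, or -0.94 on the log2 scale. That minimum is a larger share of the smaller wild-type library, which favours precursors with a high wild-type share. Over all 47 precursors compared the median ratio was 1.12. Values given as relative to the median ratio use 0.520, so they depend on this choice of precursors. Relative to 0.520, 28 were higher and 17 lower in fiery. With only tags longer than 35 nt the ratio was 20.9 for mir398c, 6.30 for mir398b, 8.67 for mir472a, 2.77 (1.65 to 5.01) for mir863 and 0.201 for mir172a. It was 19.9 for mir164b, 10.5 for mir156c, 9.26 for mir160a, 4.18 for mir824, 4.14 for mir156d and 3.67 for mir169a. Of those lower in fiery, it was 0.0733 for mir166b, 0.0321 for mir319a, 0.0355 for mir319c, 0.0353 for mir171b and 0.0880 for mir390a. No ratio could be given with those tags for mir395b, mir447b, mir393a, mir447a, mir414 and mir845b. Of the 35 precursors compared with those tags, 15 were higher and 17 lower in fiery.

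**Figure D4:**
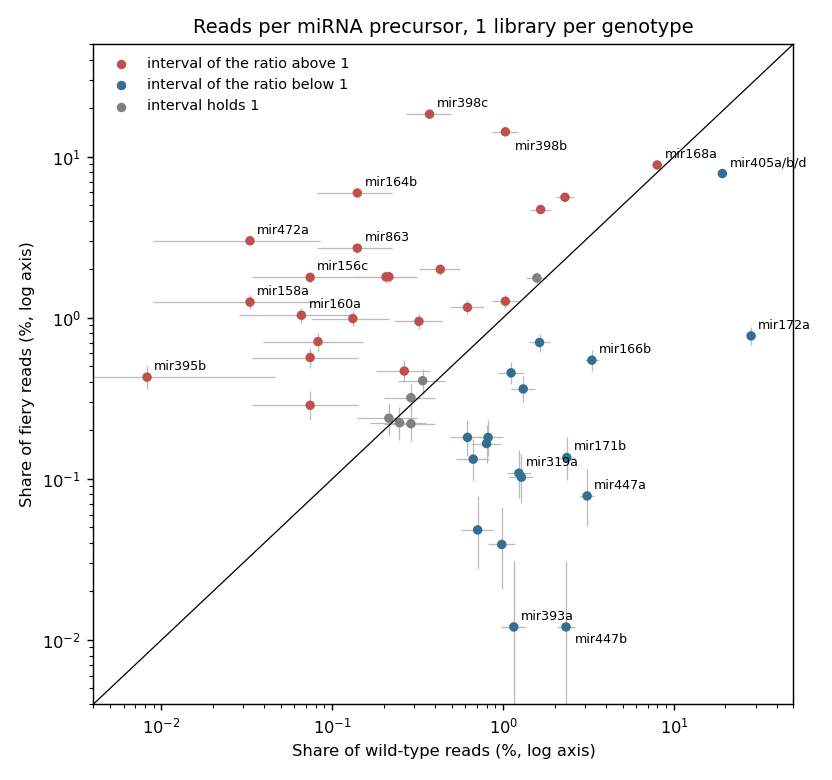
Share of each library's reads per precursor, wild type on the horizontal and fiery on the vertical log axis, for 47 precursors with at least 100 reads in both libraries together. Bars are exact 95% intervals for counting error, the line marks equal shares, and colours mark whether the interval of the ratio lies above 1 (23, red), below 1 (18, blue) or holds 1 (6, grey).

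By function, the pooled share of the copper-response precursors was 13.7-fold higher in fiery (12.2 to 15.4) and rested on mir398c and mir398b, with 3 of 3 members higher (mir398c, mir398b and mir408, the last at 1.23-fold with an interval of 1.00 to 1.51). The pooled value was 26.3 relative to the median ratio and 6.84 (6.05 to 7.77) with only tags longer than 35 nt. The median ratio of this list was at percentile 75.5 of random lists matched on reads. With 3 members, which the random lists could also draw, this does not decide whether the list as a group was set apart. The phosphate and sulfate list was 3.23-fold higher (2.13 to 5.10), with mir395b (142 of its 221 fiery reads and 1 of its 25 wild-type reads) as its only member of at least 100 reads, so that it rested on that precursor. The phase-change and flowering list had a pooled ratio of 0.185 (0.175 to 0.195), and mir172a alone held 90.2% of its wild-type reads. Of its 6 members, 2 were higher (mir156c and mir156d) and 2 lower (mir172a and mir172d). Its pooled ratio was 0.774 with only tags longer than 35 nt. In the leaf and organ patterning list, mir164b was higher and 5 of 6 members were lower, among them mir166b (0.165) and mir319a (0.0877). The pooled ratio of that list was 0.787 (0.734 to 0.844), which became 1.51 relative to the median ratio and 0.378 (0.352 to 0.407) with only tags longer than 35 nt.

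The auxin list had 2 higher and 2 lower members of 6, mir160a and mir167b (7.63) against mir393a and mir390a. Its pooled ratio was 0.784 (0.695 to 0.885), which also became 1.51 relative to the median ratio. For self-regulation of the pathway, mir168a had a ratio of 1.11 (1.03 to 1.20) and mir168b of 0.292 (0.205 to 0.416). The pooled ratio of that list was 1.05 (0.975 to 1.12), and it was 2.01 relative to the median ratio and 0.475 with only tags longer than 35 nt. Among triggers of secondary siRNAs, mir390a was lower, and the pooled ratio was 0.371 (0.288 to 0.478), or 0.183 with only tags longer than 35 nt. The pooled ratios of the lists by cutting mode were 1.08 (0.991 to 1.19) for short loop-to-base, 0.109 (0.0883 to 0.133) for sequential loop-to-base and 1.19 (1.15 to 1.23) for base-to-loop families. With only tags longer than 35 nt these were 0.651, 0.0445 and 1.60, and relative to the median ratio 2.08, 0.209 and 2.29.

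The fifth question was whether the precursors were cut at the same sites in both libraries. The main end lay at the same position within 1 nt in 22 of 31 precursors with at least 30 reads in each, among them mir168a, mir398b, mir166a, mir166b, mir171b, mir172b, mir390a, mir408 and mir822. It was identical in 21 of them, and mir161 differed by 1 nt. The 22 include mir169k, whose shared main end lay upstream of the annotated precursor. They also include mir405 and mir416, with main ends 25 and 28 nt beyond the base-side cut in tags of 27 and 26 nt. The main end of mir398c counted as the same, but in wild type it rested on 7 reads, as many as 2 positions over 200 nt away. In these 22 the share of the main end was higher in fiery in 15, with a median difference of 6.32 percentage points. In mir171c the main end was at the base-side cut in fiery (286 of 385 reads) and at the loop-side cut in wild type (42 of 75 reads, chromosome 1, position 22930115). In mir172a it was at the base-side cut in fiery (42.2% of its reads) and 30 nt beyond it in wild type (29.0%), in a tag of 26 nt. Both libraries used these 2 sites, since fiery also had 10.2% of its mir172a reads 30 nt beyond the cut. Wild type had 2.04% at the cut. In mir319a the main end was at the loop-side cut in fiery (11 of 36 reads, all in the tag of 28 nt with the limit given above) and 44 nt upstream of it in wild type (64 of 150). In mir319c it was 23 nt upstream of the loop-side cut in fiery (8 of 34) and at the base-side cut in wild type (39 of 155), but 13 fiery reads lay within 1 nt of the base-side cut, so that both libraries used the same 2 sites. mir156b, mir167a and mir159b had their main end at the base-side cut in fiery and elsewhere in wild type, where it rested on 9, 8 and 10 reads. For mir167a this difference has no weight, since its base-side cut would give a tag of 47 nt, a length absent from wild type. In mir156b, fiery also had 15 and 18 reads 33 and 34 nt beyond the cut, where wild type had 5 and 6. In mir775 and mir779 the wild-type main end lay outside the annotated precursor, upstream of it. The loop-side share could be set side by side in 25 precursors, and its intervals did not overlap in 4. These were mir171c (16.9% and 97.7%), mir319c (23.5% and 0%), mir408 (1.93% and 12.3%) and mir168a (0% and 0.557%), in fiery and wild type.

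The last question was how conserved families compared with the other, mostly younger, families. In fiery, fragments of conserved precursors had a more defined main end. The main end held a median of 75.0% of the reads in conserved precursors and 43.2% in the others, at percentiles 99.4 and 0.05 of random lists matched on reads. In wild type the medians were 63.6% and 50.9%, at percentiles 89.8 and 13.4, within the range of random lists. The difference of 31.9 points in fiery was 13.5 with at least 100 reads per precursor. That of 12.7 points in wild type was 4.30 with each family counted once, 20.2 with at least 100 reads and 33.4 with only tags longer than 35 nt. The main end was at the base-side cut in 28 of 31 conserved and 6 of 19 other precursors in fiery, and in 17 of 26 and 2 of 9 in wild type. Examples with the most reads were mir398c, mir398b and mir168a (conserved), and mir405 and mir779 (other), the last with 20.0% of its fiery reads at its main end. The median loop-side share was 0.452% for conserved and 6.25% for other precursors in fiery, and 0% for both in wild type. The fiery difference of -5.80 points was -0.280 with a minimum of 10 reads per precursor, so it depended on that minimum. Conserved precursors held 64.3% (63.7 to 64.8) of the fiery reads and 62.4% (61.6 to 63.3) of the wild-type reads, a ratio of 1.03 (1.00 to 1.06), and the others gave a ratio of 0.951 (0.919 to 0.984). Relative to the median ratio they were 1.98 and 1.83. With only tags longer than 35 nt they were 0.964 and 1.17, so that the order of the 2 groups was not stable.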

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

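The tests of explanations for mir398 in this part were chosen after the result was seen. The 3 signals given first lay outside the comparisons, in tags away from the named precursor or on the other strand, and had a higher share in fiery than in wild type by their counting interval. Tags named mir398c but over 200 nt from the precursor had a ratio of 4.03 (2.87 to 5.81, 1.23% against 0.305% of the reads). They had 245 distinct 5′ ends on chromosome 5 between 4695286 and 4697286, on the plus strand, and the most frequent end, with 9 reads, lay opposite NRT2.7. Tags antisense to mir835 had a ratio of 4.90 (2.00 to 15.6, 67 against 5 reads) with 5 distinct ends, the main one at chromosome 1, position 28544833. Tags named mir863 over 200 nt from the precursor had a ratio of 3.33 (2.01 to 5.87, 155 against 17 reads), with 68 distinct ends.

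The pattern weighed here is the higher share of mir398b and mir398c in fiery. A different composition of the wild-type library, with its many short tags, would bring both ratios to 2 or less once only tags longer than 35 nt are counted, and the lower of them, that of mir398b, was 6.30 (5.26 to 7.62), which argues against composition as the whole cause. Amplification of a single fragment would leave the other ends of these precursors with a ratio of 2 or less. Reads near the 2 precursors but over 1 nt from the base-side cut had a ratio of 42.6 (23.1 to 89.1, 1166 against 10 reads). In fiery they lay at 74 distinct distances from the precursor start, a distance shared by both precursors being counted once. The 8 wild-type reads of mir398c near its precursor were all within 1 nt of the cut, so the 10 reads came from mir398b. The mutant genotype stays open, and it cannot be told apart from other differences between these libraries, such as plants, RNA or PCR, because there was 1 library per genotype.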

How the results depend on the processing

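Of the summary values under the alternatives, 122 stayed within their interval or within 1.5 times for a count, 15 moved and 0 reversed. This rule was loose for medians over few precursors. The wild-type sequential loop-to-base median counted as unmoved, though it went from 70.8% to 0% with only tags longer than 35 nt. So did the wild-type short loop-to-base median, at 20.1% and 60% with at least 10 reads per precursor. The 122 are therefore no measure of stability. The pooled ratios of the lists were not counted here. Some of them crossed 1 relative to the median ratio or with only tags longer than 35 nt. The 24 named ratios kept their direction with an interval apart from 1 in 112 of 112 cases. Of these, 24 could not differ, since a lower minimum of reads leaves a ratio as it is, and the 24 were picked as the most extreme, so this is a weak check. They could not be computed for 2 precursors without the most abundant ones and for 6 with only tags longer than 35 nt. That setting was chosen after seeing the data, as was the one without precursors whose base-side cut could not be read, where 21 of 28 main ends were the same. So was the bootstrap interval for conserved minus other families, which replaced a tolerance of 10 points and no longer counted 13.5 points (fiery, at least 100 reads) and 33.4 points (wild type, tags longer than 35 nt) as moved, against 31.9 and 12.7. Precursors measured were 122 in wild type with a minimum of 1 read, 31 in fiery and 19 in wild type with a minimum of 100, and 47 in wild type with only tags longer than 35 nt. Main ends at the base-side cut numbered 20 in fiery and 10 in wild type with at least 100 reads per precursor, where fewer precursors enter. With distinct tags counted once, which removes the read numbers, they numbered 2 and 8, and the median share of the main end was 7.69% and 14.3%. With reads pooled over precursors, the wild-type loop-side share was 4.52% over all precursors and 0.319% in the base-to-loop list. With a minimum of 30 reads in both libraries together, 36 precursors were higher and 34 lower in fiery, of 81. With only tags longer than 35 nt, 15 were higher and 17 lower, of 35. Apart from the settings that change how many precursors or reads enter, the cause was not tested. Precursors with the same main end made up 16 of 20 with those tags and 15 of 20 with the fiery library thinned to the wild-type depth. No paired analysis was possible because there was 1 library per group.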

Other observations

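In this part the test of the lower stem was set before its result was seen, and the other tests were chosen after the result was seen.

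Among the precursors outside the conserved list, some had a defined end away from both annotated cuts. mir416 had its main end 28 nt beyond the base-side cut in both libraries, with 63.1% of the fiery and 48.0% of the wild-type reads, in a tag of 26 nt, the shortest length present, so that its place next to the primer limits what it shows. mir824, whose product targets the MADS-box gene AGL16, had 96.6% of its fiery reads at the base-side cut, so that the other families were not uniform. mir844 had 79 fiery and 26 wild-type reads on the antisense strand, with 60 distinct ends along PAB4.

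The ends 20 to 23 nt beyond the base-side cut in 6 precursors may mark a first cut 1 duplex length further down a long lower stem. If so, these precursors would have more paired bases below the duplex than precursors with the main end at the base-side cut. In RNAfold structures they had a mean of 17 ± 1.87 paired bases of 20 (SD, 5 precursors), against 10.8 ± 4.12 (SD, 38 precursors), a difference of 6.18 with p = 0.00315 in an exact two-sided permutation test over precursors. mir394b was left out of this after the first result, with all 6, was seen (6.02, p = 0.00161), because its base-side cut could not be read in wild type. Related precursors are not independent, and this compares precursors, not genotypes. All 5 belong to the other families. In fiery, 28 precursors with the main end at the base-side cut were conserved and 6 were not. The difference in pairing is therefore not separated from conservation of the family. The tags of the 6 precursors at these ends are 27 to 33 nt long and lie close to the primer. Primer-adjacent products common to all primers would appear in other precursors too. Of these, 27 where such an end could be read had a median of 0.503% of their fiery reads there (0 to 18.1%). mir405, not among the 27, had 22.9% there. Only fiery reads in this window were used, while mir447b and mir394b had these ends in wild type. Products next to some primers only, or at other distances, are therefore not excluded.

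In wild type, 96.9% of the mir172a reads were in tags of 35 nt or less, against 53.2% for the other precursors, and 3314 of these 3321 reads shared 1 3′ end. More cutting of the mir172a precursor in wild type would lower its base-side reads in fiery by the factor seen in all its reads, to a ratio under 0.1, and the ratio at the base-side cut was 0.569 (0.418 to 0.780, 109 against 70 reads), which argues against this as the cause of the whole difference. Products next to the primer could be a source of the short tags, but with only tags longer than 35 nt the ratio was 0.201 (0.154 to 0.262), between the bounds set for and against this explanation, so it stays open.

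FIERY1 of Arabidopsis is a nucleotidase whose loss inhibits 5′-to-3′ exoribonucleases of the XRN family. A hypothesis from this is that trimming of cut fragments would leave more reads 1 nt beyond the base-side cut in wild type, if the mutant carries a lesion in that gene. Over 13 precursors with at least 30 reads at these 2 positions in each library, the median difference in that share, wild type minus fiery, was -1.55 percentage points (interval of the median -3.90 to 1.11). It was higher in wild type in 4 and lower in 8, among them mir398b (5.22% in wild type and 15.4% in fiery) and mir408 (31.6% and 43.3%), while the largest difference, in mir172d (24.0% and 0%), went the way of the hypothesis. The interval holds 0, so the hypothesis stays undecided at this number of precursors. This measure replaced a first test of the mean difference, by which the hypothesis had been judged not to hold.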
